A study of Mus musculus with 4 samples.

How the data were processed

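Total RNA of sorted TFR and non-TFR regulatory T cells from control and Prdm1 knockout mice was labelled and hybridized to Affymetrix Mouse Gene 2.0 ST arrays, per the labels. There were 4 samples in 4 groups, each sample 1 array, and each was assigned to its group by its title. The number of mice behind each array, the animals' sex and the batches of sorting and hybridization are not given in the sources used here.

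The deposited table holds 1 log2 value per transcript cluster (called a probe here) and array, as made by the authors; the log2 scale was inferred from the values, which ran from 2.23 to 13.8. MAS5 is named in the submitters' processing notes without a version, role or scaling target, and background correction and summarization are not given in the sources used here. The table gives no detection calls. Deposited medians were 5.69 in control TFR, 5.68 in knockout TFR, 5.58 in control non-TFR and 5.58 in knockout non-TFR cells. They spanned 0.105, more than the limit of 0.1 set before the data were examined, so that quantile normalization of all 41345 probes with limma 3.58.1 in R 4.3.3 was applied on top of the deposited values. It makes the distributions of the arrays equal, which removes a real difference common to most genes together with a technical one. The values were already on a log scale, so no pseudocount was used.

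Probes were named from the platform annotation: 23521 had 1 gene, 1814 had several and 16010 were not named there. Of the first, 23328 matched the gene table of the reference annotation by Entrez identifier, no symbol changed, and 193 kept the annotation's symbol. Only probes with 1 gene were used for genes. For the 1082 genes with more than 1 probe the probe with the highest mean over the 4 arrays was taken, leaving 22180 genes. A gene counted as expressed when its mean was above the median of all genes (5.91), which left 11090. No genome build is given for the probes, and no coordinates are reported. Near-identical genes can share signal on these arrays. Ly6c1 with Ly6c2 and Hspa1a with Hspa1b are named as uncertain, and other gene families were not examined for this.

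With 1 array per group, every comparison is the log2 difference of a pair of arrays, without a test or p-value across genes, and the number of arrays limits the precision. TFR was compared with non-TFR in each genotype and knockout with control in each population. Genes at least 2-fold apart were counted. Correlations across genes and shared 2-fold genes were set beside the number that independent lists would share. The difference of the population differences between genotypes was computed per gene. An additive model of population and genotype, which would leave 1 residual degree of freedom, was not fitted.

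The 28 gene lists (T cell programmes, pathways and markers of other cell types) were fixed before the data were examined, from general knowledge. Prdm1, Foxp3, Cxcr5, Pdcd1 and Cd4 were left out of list statistics. Members not measured by a probe with 1 gene were left out, as in the mitochondrially encoded list, where this removed all of them. Each list's median difference was placed among 10000 random lists of the same size, drawn with replacement within 20 bins of mean expression, and called outside the chance range below percentile 2.5 or above 97.5. Of 108 list and comparison pairs 5.4 would lie outside if list members were as unrelated as the genes of random lists, and 51 did. Members of a programme can move together between any pair of samples, and lists and comparisons overlap. The excess therefore does not exclude chance differences between single samples. The genes named were, for each comparison, the 10 expressed genes with the highest and the 10 with the lowest difference among ordinary symbols, up to 4 members with the largest difference per list, the 10 genes with the largest shared differences in each direction, the target and gate genes. Immunoglobulin and T cell receptor segments, predicted genes, small RNAs and olfactory receptors were left out of naming. Genes such as Il2ra in TFR cells that fall outside this rule in a comparison, and those with the largest differences between genotypes, were chosen after their values were seen.

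The counting and list steps were tested on simulated data standing for the TFR genotype comparison, with 200 of 11090 genes changed. The noise SD was set to 0.160 per array. The 2-fold count found 12% of genes changed by 0.75 on the log2 scale, 98.5% of those changed by 1.5 and 100% of those changed by 2.5. It called 0 unchanged genes, but noise set this small against the 2-fold limit makes false calls rare by construction. The noise of the measured genes is not known without replicates. The simulation therefore checks the steps and does not estimate false calls in the 2-fold counts reported here. Alternatives were the values as deposited, cyclic loess, centring on the 75th percentile, no filter or a stricter filter on dim genes, the mean of all probes of a gene, a floor at the 20th percentile, a threshold of 1.5-fold, list means, and lists without shared members. Alternatives added after seeing the data were the effector Treg list without Gzmb and Il10, normalization over named probes only, and counts without the cell cycle list. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.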

Results

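Gene expression was measured in regulatory CD4 T cells of mice taken 7 days after immunization with the hapten-protein conjugate NP-OVA in complete Freund's adjuvant. Follicular regulatory T cells (TFR cells) carried PD1, CXCR5 and a Foxp3-driven YFP reporter, and the other regulatory T cells (non-TFR cells) carried the reporter and lacked CXCR5. Each population was sorted from control mice, in which Foxp3 drives YFP and Cre, and from knockout mice that in addition had both alleles of Prdm1 floxed. Prdm1 encodes the transcriptional repressor Blimp-1, and in these mice its floxed alleles are the target of Cre in Foxp3-expressing cells. The 4 groups were represented by 1 Affymetrix Mouse Gene 2.0 ST array each, and no difference below therefore has a replicate check. Differences are given on the log2 scale. Genes at least 2-fold apart were counted, and the highest and lowest genes ranked, without a test among the 11090 genes in the brighter part of the array (expressed genes), whereas list counts and medians cover all measured members. No fold is given where the dimmer value lay below the expression limit of 5.91, since no detection calls show whether it was above background, and such differences can be compressed. A gene list was called outside the chance range when its median lay outside the middle 95% of 10000 random lists of matched expression, as a description of these arrays.

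The targeted gene, Prdm1, had a level of 8.21 in control TFR cells and 7.32 in knockout TFR cells, a difference of -0.89 (1.85-fold lower). In non-TFR cells its level was 7.80 in the control array and 7.59 in the knockout array, a difference of -0.21 (1.15-fold lower). The middle 95% of expressed genes spanned -0.50 to 0.56 in the TFR genotype comparison and -0.44 to 0.68 in the non-TFR comparison, so Prdm1 lay outside that range in TFR cells and inside it in non-TFR cells. The Prdm1 value is 1 summary over the transcript, and the sources used here do not give which exons were deleted or which of them the probes cover. Signal from outside the deleted part checks nothing about the deletion. Among the genes that set the sort gates, Cxcr5 was 1.46 higher in TFR than in non-TFR cells of the control and 1.49 higher in the knockout, and Pdcd1, which encodes PD1, was 2.41 and 1.72 higher. Foxp3 had levels of 12.36 in control TFR cells, 11.87 in knockout TFR cells, 12.45 in control non-TFR cells and 12.42 in knockout non-TFR cells. Cd4 lay between 11.02 and 11.33 in the 4 arrays. These genes served as checks of the sort and are not findings between the gated populations.

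**Figure D1:**
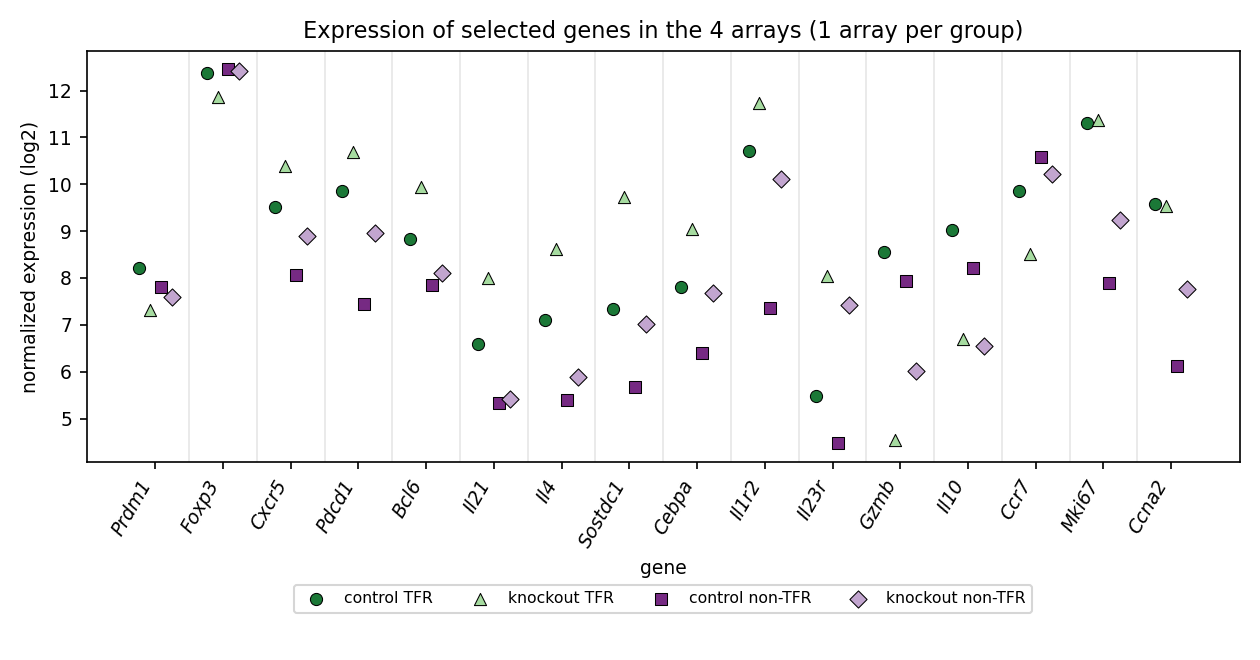
Normalized expression (vertical axis, log2) of 16 genes (horizontal axis) in the 4 arrays, with 1 symbol per array and no error bars because each group has 1 array; the genes were picked for display after their values were seen. Gzmb had a level of 8.54 in control and 4.55 in knockout TFR cells, and Il23r had 5.49 and 8.04.

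The first comparison asked what separates TFR from non-TFR regulatory cells in control mice. The TFR gate required PD1 as well as CXCR5, and no PD1 requirement is given for the non-TFR gate. Differences that go with PD1 and those that go with CXCR5 therefore cannot be told apart in the population comparisons. Cell division genes were far higher in TFR cells: of 33 measured cell cycle genes, all 33 were higher and 30 were at least 2-fold higher, with a median difference of 2.205. Nusap1, a mitotic spindle protein, was 3.97 higher, the mitotic kinase Cdk1 was 3.61 higher, and the proliferation marker Mki67 was at 11.31 in TFR and 7.90 in non-TFR cells (10.7-fold). The highest difference among expressed genes was that of Prr11, a cell cycle gene outside the list, at 4.24. The T follicular programme was also higher, with 10 of 26 measured members at least 2-fold higher, none 2-fold lower and a median of 0.89. Its leading members were the decoy interleukin-1 receptor Il1r2 (3.34 higher, 10.2-fold), the interleukin-1 receptor antagonist Il1rn (2.27), the transcription factor Maf (1.81) and the cytokine Il4 (1.71). Bcl6, the transcription factor of follicular T cells, was 0.98 higher, just short of 2-fold.

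Genes of naive and resting T cells were lower in control TFR cells. Of 18 measured members 17 were lower and 7 at least 2-fold lower, with a median of -0.85. They included Dapl1 (-2.02), the chromatin organizer Satb1 (-1.85) and S1pr1 (-1.57), the receptor that T cells use to leave lymphoid organs. Among expressed genes Ly6c2 had the lowest difference at -2.77 (6.84-fold lower). Its near-identical neighbour Ly6c1, a member of the naive list below the expression limit, was at -3.16, and the assignment of signal between these genes is uncertain. Cnn3 (-2.23), the adenylate cyclase Adcy6 (-2.22) and the cytotoxic pore protein Prf1 (-1.79) were also among the 10 lowest. In all, 458 genes were at least 2-fold higher and 151 at least 2-fold lower in TFR cells, and 572 and 104 without quantile normalization.

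Activated and effector regulatory genes were higher in control TFR cells too. The effector Treg list had a median of 0.61, with 8 of 31 measured members at least 2-fold higher, among them the inhibitory receptors Tigit (1.87) and Lag3 (1.41) and the chemokine receptors Cxcr3 (1.74) and Ccr6 (1.27). Inhibitory receptors (median 0.58), T helper and effector cytokines (0.52), the IL-23, IL-6 and Th17 axis (0.47), costimulatory receptors (0.41) and T cell transcription factors (0.31) lay above the chance range. Lower than the chance range were heat shock genes (median -0.31), cholesterol synthesis (-0.24), interferon response genes (-0.21), genes reported as repressed by Blimp-1 (-0.21) and ribosomal proteins (-0.18). The list of T cell receptor induced and immediate early genes also lay below it (-0.24). Of its 22 members 17 were lower and 5 higher, Irf4 (0.73) and Egr3 (0.61) among the higher. The Treg core list had a median of 0.19, at percentile 98.5 of random lists, with 13 of 21 members higher. Without members shared with other lists the Treg core median was -0.01, and inhibitory receptors (0.07), cytokines (0.19), the Th17 axis (0.29) and transcription factors (0.18) also lay inside the chance range. The Treg core also lay inside it as deposited (0.21) and under 4 other settings, the Blimp-1 list as deposited (-0.08), with 75th percentile centring (-0.18) and as a mean (-0.09), ribosomal proteins over named probes only (-0.13), and the Th17 axis (0.17) and cytokines (0.33) over members above the 75th percentile of expression.

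The same comparison in knockout mice, on the other pair of arrays, asked whether TFR and non-TFR cells of that genotype differ in the same genes. Cell cycle genes were again higher, with 28 of 33 at least 2-fold higher and a median of 1.77, led by Nusap1 (2.81) and Cdk1 (2.61). The T follicular programme had a median of 0.73 and 12 of 26 members at least 2-fold higher. Its top members were Il1rn at 3.40, Il4 at 2.74, the secreted Wnt and BMP antagonist Sostdc1 at 2.70 (6.49-fold) and the helper cytokine Il21 at 2.58. Bcl6 was 1.84 higher (3.59-fold), and the DNase Dnase1l3 was 3.04 higher. Naive and resting genes were lower in all 18 measured cases, with 8 at least 2-fold lower and a median of -0.98, including Dapl1 (-2.27), Igfbp4 (-2.07), Satb1 (-1.95) and the lymph node homing receptor Ccr7 (-1.69).

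Several regulatory genes were lower in knockout TFR than in knockout non-TFR cells. The Treg core list had a median of -0.23, with 14 of 21 members lower and 4 at least 2-fold lower, including the integrin Itgae (-1.43) and the interleukin-2 receptor chain Il2ra (-1.23), while Tigit was 1.59 higher. The effector Treg median of 0.15 lay at percentile 97.1, inside the chance range, and was 0.20 at percentile 99.4, outside it, without Gzmb and Il10. The effector Treg list also lay above it as deposited (0.29), with 75th percentile centring (0.14) and with cyclic loess (0.17). The same held as a mean (0.20) and over members above the median expression (0.18). Lists above that range also included germinal centre B cell markers (0.36), inhibitory receptors (0.36), glycolysis (0.31) and oxidative phosphorylation (0.15). Lists below it included T cell receptor induced and immediate early genes (-0.41), genes reported as repressed by Blimp-1 (-0.36), interferon response genes (-0.30) and ribosomal proteins (-0.23). The germinal centre B cell median was -0.05 over members above the median expression and lay inside the range under 3 other settings, and that of inhibitory receptors was -0.10 without members shared with other lists and inside the range as a mean (0.24). Oxidative phosphorylation lay inside it as deposited (0.18), with 75th percentile centring (0.035), with cyclic loess (0.11), as a list mean (0.12) and with the mean of all probes (0.12), and the Treg core with the mean of all probes (-0.13).

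In the knockout, 336 genes were at least 2-fold higher and 152 at least 2-fold lower in TFR cells. Without quantile normalization the split was 443 higher and 103 lower, on a scale where the median of all genes was 0.14 in this comparison and 0.13 in the control, against 0.014 and 0.021 after normalization. The differences between the populations were alike in both genotypes, with a Pearson r of 0.80 and a Spearman rho of 0.73 across genes, which are not independent replicates. These 2 comparisons share no array. Genes at least 2-fold higher in both numbered 258, against 13.9 for independent lists, and genes at least 2-fold lower in both numbered 78, against 2.07. No gene was 2-fold apart in opposite directions. Among genes high in both were Depdc1a, Dnase1l3, Mastl, Brip1 and Knl1, and among genes low in both were Ly6c2, Dapl1, Satb1, Tlr7 and Sorcs2.

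Within TFR cells, the comparison of knockout with control asked how the follicular population differs with the Prdm1 genotype. The cytotoxic protease gene Gzmb had by far the lowest difference at -3.998, from 8.54 in the control to 4.55 in the knockout. The knockout value lay near the floor of 4.17, above 22.1% of genes, and was not shown to be above background, so that the size of this difference is uncertain. The anti-inflammatory cytokine Il10 followed at -2.33 (5.03-fold lower). Il23r, the receptor chain for interleukin-23, had the highest difference at 2.55, followed by Sostdc1 at 2.39 (5.23-fold) and the membrane protein Stom at 1.91 (3.75-fold). Follicular helper genes were higher in the knockout: 6 of 26 measured members of the T follicular programme were at least 2-fold higher and none 2-fold lower, with a median of 0.55. They included Il4 (1.51), Il21 (1.41), the transcription factor Cebpa (1.24), Bcl6 (1.12, 2.17-fold) and Il1r2 (1.03).

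Regulatory genes were mostly lower in knockout TFR cells. Of the 21 Treg core members 16 were lower, none was 2-fold apart, and the median of -0.29 lay below that of all 10000 random lists. Gpr83 (-0.80), Lrrc32 (-0.78), the ectoenzyme Entpd1 (-0.74) and Il2ra (-0.67) were among the lower members, and Gpr15 was 0.93 higher. Foxp3 itself differed by -0.49. The effector Treg list had a median of -0.18, with 20 of 31 members lower and Gzmb, Il10 and the chemokine receptor Ccr2 (-1.29, with a mean below the expression limit) at least 2-fold lower. Without Gzmb and Il10, a choice made after the values were seen, that median was -0.08 at percentile 1.89, still outside the chance range. Over members above the 75th percentile of expression, or without members shared with other lists, the effector Treg median was also -0.08 and lay inside it.

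Other genes with lower values in knockout TFR cells were Neb (-1.89), Ccr7 (-1.34), the transcription factor Ets2 (-1.28), the protease inhibitor Ctla2a (-1.26) and the death ligand Fasl (-1.24). Genes of naive and resting cells had a median of -0.25, with 15 of 18 lower. Of 16 measured genes reported as repressed by Blimp-1, 12 were lower, among them Ccr7, the transcription factor Bach2 (-0.996) and Ifng (-0.79), and 4 were higher, among them Bcl6 (1.12). Their median of -0.11 lay at percentile 1.83, but inside the chance range as deposited (-0.10), with 75th percentile centring (-0.11), with a floor (-0.08) and over named probes only (-0.11). This list shares 5 measured genes with the naive and resting list, among them Ccr7 and Bach2, so the shifts of these lists are not separate. T cell receptor induced and immediate early genes had a median of -0.26, led by the nuclear receptors Nr4a1 (-0.98) and Nr4a3 (-0.76). Interferon response genes had one of -0.31, led by Oas2 (-0.69). Glycolysis genes were higher, with 12 of 14 members above 0 and a median of 0.21. The heat shock genes Hspa1a (1.38) and Hspa1b (1.09) were at least 2-fold higher. The median of their list, 0.06, lay inside the chance range, and its mean of 0.24 lay above it. Hspa1a and Hspa1b are near-identical genes, so that the assignment of signal between them is uncertain. Cell cycle genes did not separate the genotypes in TFR cells, with a median of 0.05 and no member 2-fold apart. In total 49 genes were at least 2-fold higher and 26 at least 2-fold lower. Among genes above the 75th percentile of expression the balance turned, with 8 higher and 14 lower.

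**Figure D2:**
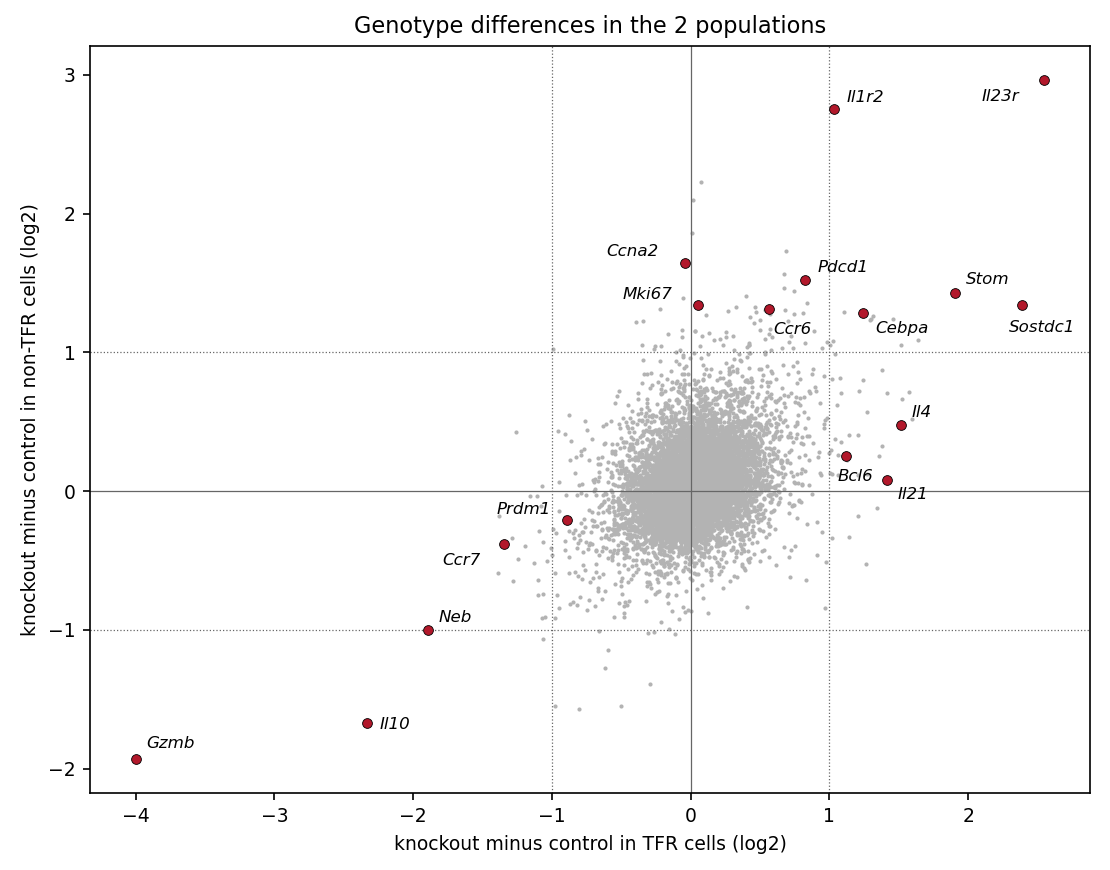
Log2 difference of knockout minus control in TFR cells (horizontal axis) against that in non-TFR cells (vertical axis), with 1 grey point per expressed gene, dotted lines at 2-fold, and red points for 17 genes labelled after their values were seen. Il23r lies at the top right (2.55 and 2.96), Gzmb at the bottom left (-3.998 and -1.93), and Il21 and Bcl6 lie to the right near 0 on the vertical axis (0.08 and 0.25), Il21 with both non-TFR values below the expression limit.

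Within non-TFR cells, the comparison of knockout with control asked the same question outside the follicular gate. Il23r was again the gene with the highest difference at 2.96, from 4.47, a control value near the floor, to 7.43, followed by Il1r2 at 2.76 (6.75-fold), Prr11 at 2.22 and Dscam at 2.10. Gzmb (-1.93, 3.81-fold lower) and Il10 (-1.67, 3.19-fold lower) again had the lowest differences, ahead of the death-associated kinase Dapk1 (-1.55) and Cnn3 (-1.55). Cell cycle genes were higher in the knockout in all 33 cases, 7 of them at least 2-fold, with a median of 0.58. Ccna2 (1.65), Mki67 (1.34), Cdk1 (1.33) and Nusap1 (1.27) led them. In total 86 genes were at least 2-fold higher and 14 at least 2-fold lower.

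Follicular and effector genes were higher in knockout non-TFR cells as well. The T follicular programme had a median of 0.40 with 24 of 26 members above 0, led by Il1r2, Sostdc1 (1.34) and Cebpa (1.29), whereas Bcl6 differed by 0.25. Il21 had values of 5.34 and 5.42 in the control and knockout non-TFR arrays, both below the expression limit and not shown to be above background, so that a difference there could not be measured. The gate genes Pdcd1 and Cxcr5 were 1.52 and 0.84 higher. The effector Treg list had a median of 0.30, with Ccr6 (1.31), Lag3 (1.27) and Cxcr3 (1.12) at least 2-fold higher and Gzmb and Il10 at least 2-fold lower. Costimulatory receptors (median 0.33, led by Tnfsf14 at 1.07), inhibitory receptors (0.31), germinal centre B cell markers (0.24), the Treg core (0.24), T cell transcription factors (0.17), the IL-23, IL-6 and Th17 axis (0.17), chemokine receptors (0.14) and genes reported as repressed by Blimp-1 (0.14) lay above the chance range. Without members shared with other lists, inhibitory receptors (0.12), germinal centre B cell markers (0.20), the Treg core (0.06), transcription factors (0.10), the Th17 axis (0.17) and chemokine receptors (0.07) lay inside the range. The Blimp-1 list was -0.12 over members above the 75th percentile of expression and inside the range with a floor (0.11), as a mean (0.07), over members above the median (0.08) and over named probes only (0.10); germinal centre B cell markers were also inside it as a mean (0.20) and over brighter members (0.21 and 0.25), chemokine receptors with a floor (0.065) and the Th17 axis above the 75th percentile (0.091).

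Lower lists in knockout non-TFR cells were naive and resting genes (median -0.37, with 16 of 18 members lower) and interferon response genes (-0.18). Cholesterol synthesis was lower too (-0.23, with 12 of 15 lower, among them Srebf2 at -0.58). So were T cell receptor induced and immediate early genes (-0.11, and inside the range as a mean of -0.063). The perforin gene Prf1 was at -0.92 and the receptor Klrg1 at -0.81. Kctd12 (-1.01) was among the 10 lowest genes, but its other probe differed by -0.13.

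The 2 genotype comparisons use different arrays, and their differences correlated across genes with a Pearson r of 0.35 and a Spearman rho of 0.28. Il23r, Stom, Sostdc1, Gna14, Krt17, Mid2, Cebpa, Slc7a10, Sema6d and Il13ra1 were among 14 genes at least 2-fold higher in both, where independent lists would share 0.380. The genes at least 2-fold lower in both were Gzmb, Il10, Neb and Sox4, where independent lists would share 0.0328, although the other Sox4 probe differed by -0.01 in TFR cells. No gene was 2-fold apart in opposite directions.

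The difference between the populations was compared between genotypes gene by gene, as the TFR minus non-TFR value in the knockout less that in the control. It was at least 2-fold higher for 31 genes and at least 2-fold lower for 72. Il21 was at 1.34, Il1rn at 1.14, Sostdc1 at 1.05, Il4 at 1.04 and Bcl6 at 0.87. The non-TFR values of Il21, Il1rn and Il4 in both genotypes, and that of Sostdc1 in the control, lay below the expression limit, so that the sizes of these terms are uncertain. Other follicular genes and cytokines were on the lower side, with Icos at -0.35, Sh2d1a at -0.19, Ifng at -1.07 and Il10 at -0.66, and the median of the T follicular programme was 0.73 in the knockout against 0.89 in the control. Maf was at -0.12 by its brighter probe, and its other probe was 2.11 higher in TFR cells of the control and 1.37 higher in those of the knockout, with opposite signs of the probes for knockout minus control in TFR cells (0.55 and -0.48). Also on the lower side were Prr11 (-2.15), Dscam (-2.09), Gzmb (-2.07), Il1r2 (-1.72), Ccna2 (-1.68), Ctla2a (-1.68), the chemokine Xcl1 (-1.61) and Mki67 (-1.29). For Prr11 and Dscam the control non-TFR value, and for Gzmb the knockout TFR value, lay below the expression limit, so these sizes are uncertain. The 4 arrays leave no error for this term, so that none of these values was tested.

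**Figure D3:**
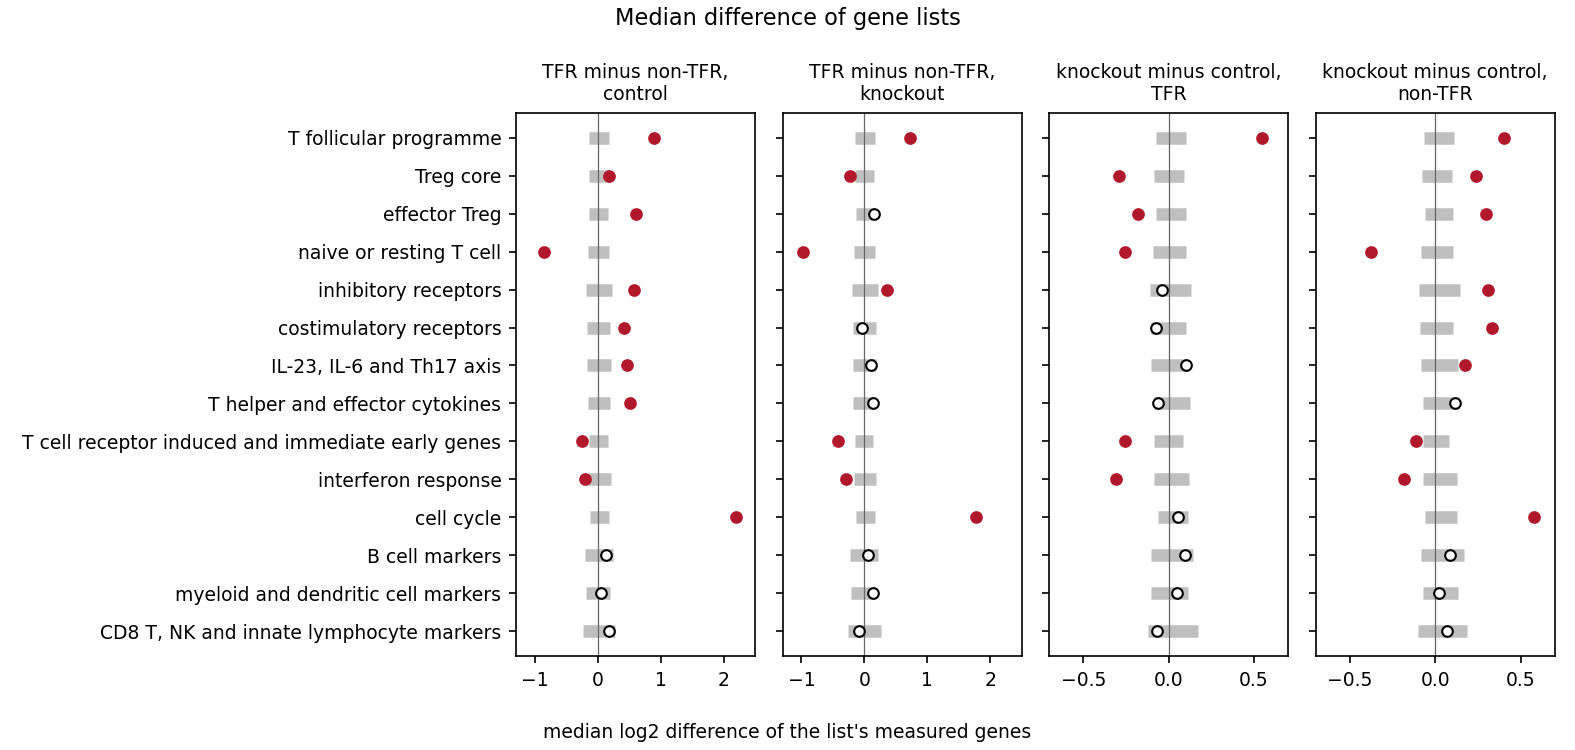
Median log2 difference (horizontal axes; the scale of the left pair of panels is wider than that of the right pair) of 14 gene lists, named at the left and picked for display, in the 4 comparisons, with grey bars for the middle 95% of 10000 matched random lists, red points for medians outside it and open points for medians inside it. Cell cycle genes lie at 2.205 and 1.77 between the populations, at 0.05 between genotypes in TFR cells and at 0.58 in non-TFR cells.

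List medians of markers of other cell types were between 5.21 and 6.38 in the 4 arrays and those of pan T cell markers between 12.38 and 12.54, but levels of different probes are not comparable and do not measure the purity of the sorts. Among single members, Ighm was at 12.58 to 13.31, Ctss at 11.64 to 12.16, Cst3 at 10.77 to 10.93, Cybb at 8.32 to 10.73, Nkg7 at 9.12 to 10.42, Edem2 at 9.83 to 10.13, Xbp1 at 9.76 to 9.91, Cd8b1 at 8.73 to 9.42 and Cd79b at 8.08 to 8.42. Medians of the B cell, plasma cell, myeloid, CD8 and NK, erythroid, stromal and pan T cell lists lay inside the chance range in all 4 comparisons. Over expressed members only, B cell markers lay above it in control TFR cells (median 0.70 over non-TFR cells) and in knockout non-TFR cells (0.31 over control). On the same basis CD8 and NK markers lay above it in control TFR cells (0.49 over non-TFR cells) and knockout non-TFR cells (0.31 over control), and below it in knockout TFR cells (-0.34 against control). As list means, B cell markers (0.28 over non-TFR cells in the control and 0.20 over control in knockout non-TFR cells), CD8 and NK markers (-0.11 and 0.22 over control in knockout TFR and non-TFR cells) and myeloid markers (0.20 over non-TFR cells in the knockout) lay outside it too. Above the 75th percentile myeloid markers did so at 0.49 in that comparison and at 0.26 over control in knockout TFR cells. Of 23 measured myeloid markers only 5 were expressed, and fewer lay above that percentile, so these values rest on few genes. Germinal centre B cell markers, which share Bcl6 and S1pr2 with the T follicular programme, had a median of 0.04 over control in knockout TFR cells, inside the range. They lay above it there as a mean (0.22), over expressed members (0.27) and above the 75th percentile (0.54), with only 4 of 8 measured members expressed. Single members moved with the groups described above: Cd22 was 2.28 and 2.22 higher in TFR cells of control and knockout and 1.00 and 1.06 higher in the knockout in TFR and non-TFR cells. Cybb was 2.01 higher in control TFR cells and 1.40 higher in knockout non-TFR cells, Cd68 was 1.20 higher in knockout TFR cells, and the NK-associated gene Nkg7 was at -0.96 in knockout TFR cells. The mitochondrially encoded list had 0 members measured by a probe with 1 gene.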

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

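Of the tests in this part, those on the gate and on genes near Prdm1 were set before their results were seen; the tests of array noise, of lost CD8 T, NK or effector Treg cells and of Foxp3-negative helper cells were chosen after, the test of array noise replaced counts of shared genes whose results had been seen, and the bar for excluding alleles near Prdm1 was raised after.

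Lists whose medians lay outside the chance range on opposite sides in a pair of comparisons were singled out, and these differences between groups were not tested. The Treg core list had a median of 0.19 for TFR minus non-TFR in the control and -0.23 in the knockout, which is the same contrast of 4 arrays as its medians of -0.29 for knockout minus control in TFR cells and 0.24 in non-TFR cells. The control value lay inside the range as deposited (0.21), with 75th percentile centring (0.11), with cyclic loess (0.13), as a mean (0.21) and over named probes only (0.13), and was -0.0053 without members shared between lists. The knockout value lay inside it with the mean of all probes (-0.13), and the non-TFR genotype value without shared members (0.062). The effector Treg list had medians of -0.18 in TFR and 0.30 in non-TFR cells, the first inside the range at -0.081 both without shared members and above the 75th percentile of expression. Genes reported as repressed by Blimp-1 had medians of -0.11 in TFR and 0.14 in non-TFR cells. The first lay inside the range as deposited (-0.097), with 75th percentile centring (-0.11), with a floor (-0.077) and over named probes only (-0.11). The second was -0.12 above the 75th percentile of expression, and inside the range with a floor (0.11), as a mean (0.073), over members above the median (0.081) and over named probes only (0.10).

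In knockout TFR cells, Treg core genes and Foxp3 were lower while follicular helper genes such as Il21, Il4 and Bcl6 were higher. A candidate explanation is that Foxp3-negative helper cells entered the sort, although the YFP gate would remove them. The 7 Treg-restricted genes chosen for the test had a median of -0.38 (95% bootstrap interval over genes -0.78 to -0.18), and Foxp3 differed by -0.49, which lies inside that interval. Helper cells in the sort and lower expression of these genes within TFR cells therefore cannot be told apart here. Differences between the animals or batches behind single arrays also stay open.

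Gzmb and Il10 were lower and Il23r higher in both knockout arrays. Noise that varies independently between arrays and genes is argued against as the whole cause of the 2-fold genotype differences as a set. Of 26 genes at least 2-fold lower in TFR cells 92.3% (exact interval 74.9 to 99.1%) were also lower on the other pair of arrays, where 44.2% of expressed genes were. The share was 91.7% (73.0 to 99.0%) when Gzmb, Il10 and Il23r were left out. For 49 higher genes it was 89.8% (77.8 to 96.6%) against 55.7%. These intervals treat genes as independent, which they are not, and the shares do not bear on Gzmb, Il10 or Il23r singly. Whether arrays of the same genotype share animals or a batch is not given, so shared differences of that kind were not tested. In non-TFR cells the median of 6 expressed CD8 T and NK markers was 0.31 (interval -0.24 to 0.99), with members from Eomes (-0.35) to Xcl1 (1.22). The interval spans both signs, so a loss of these cells, which the CD4 and YFP gates would remove, is not excluded there. The effector Treg list without Gzmb and Il10 had a median of 0.31 (0.14 to 0.53) in non-TFR cells. In the control the full list was higher in TFR than in non-TFR cells (median 0.61). The knockout non-TFR array lay closer to the TFR arrays than the control non-TFR array did. Such a shift would raise this list and could hide a loss of effector Treg cells, so that loss is not excluded there. In TFR cells the median of the markers was -0.34 (-0.76 to -0.10), with members from Nkg7 (-0.96) to an unchanged Cd8b1 (0.001). The median of the list was -0.081 (-0.29 to 0.13). Losses of CD8 T or NK cells and of effector Treg cells both stay open there. An untested effect of the Prdm1 genotype and differences between animals or sorts stay open in both populations. A separate test on the neighbours of Prdm1 found 1 of 200 flanking genes (Arfgef3, 0.67 and 0.91) against 116 of 10889 elsewhere at least 1.5-fold apart the same way in both (one-sided Fisher exact test, p = 0.882), where 2.13 were expected, too few to exclude alleles carried along with the floxed locus.

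The knockout non-TFR array lay closer to the TFR arrays than the control non-TFR array did, with higher cell cycle, Pdcd1 and Cxcr5 values. Noise of the shared control non-TFR array that varies independently between genes is argued against. The genotype difference in non-TFR cells correlated at r = 0.28 with the population difference of the knockout arrays, which do not include that array. The interval was 0.26 to 0.31 over genes, which are not independent, and simulation without genotype or population effects gave -0.50. Population differences would weaken the simulated correlation, so only its sign is compared. The covariance was 0.037 in the data and -0.024 in the simulation. Differences between animals or sorts that move many genes together are not addressed by this correlation and stay open. Knockout TFR cells inside the CXCR5-negative gate might also give the shift toward TFR cells. The share of TFR cells implied by 30 cell cycle genes was 11.6% (10.1 to 15.3) and that implied by 15 follicular genes 14.8% (9.92 to 29.1), a difference of -3.18 percentage points with overlapping intervals. An admixture and a changed state of non-TFR cells therefore cannot be told apart from these values. The share implied by 639 expressed genes was 20.5% (19.2 to 22.1), above the interval of the cell cycle genes. Without noise, a single admixed share as the only cause would give equal values for all sets. Noise of the arrays can move the sets by different amounts, so the unequal values do not exclude such a share. The knockout TFR array also moved in the direction of the population difference. The genotype difference in TFR cells correlated at r = 0.13 (0.10 to 0.15) with the population difference of the control arrays. Cells inside the knockout non-TFR gate cannot cause this, since that array enters neither difference. These intervals run over genes, which are not independent.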

How the results depend on the processing

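The alternatives were planned before the data were examined, except the normalization over named probes only, the counts without the cell cycle list and the effector Treg list without Gzmb and Il10, which were added after. Of 199 named gene differences of at least 2-fold, 187 stayed at least 2-fold under every alternative run on them, and none of these 199 reversed; of 51 list medians outside the chance range, 30 stayed outside. A pseudocount was not run, since the values were already log2. Depth has no measure on these arrays beyond signal: genes near the floor of 4.17 have only compressed differences, and no detection calls were used. Unless stated, the cause of a change was not tested.

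With every gene kept regardless of brightness, more genes could be counted: lower genes numbered 261 in the control and 262 in the knockout population comparison, and the genotype r was 0.23. With means above the 75th percentile fewer genes remained: higher and lower genes were 157 and 58 (population, control), 84 and 73 (population, knockout), 8 and 14 (genotype, TFR) and 38 and 1 (genotype, non-TFR), with 68 higher and 36 lower in both population comparisons and 2 higher and 0 lower in both genotype comparisons. At 1.5-fold, a looser limit by construction, they were 1147 and 639, 947 and 688, 240 and 173, and 409 and 121. As deposited, 46 genes were lower in both population comparisons, where the median of all genes was 0.13 in the control and 0.14 in the knockout.

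List medians left the outside of the chance range as follows. As deposited, the Treg core (population, control) was 0.21, genes reported as repressed by Blimp-1 were -0.079 (population, control) and -0.097 (genotype, TFR), and oxidative phosphorylation (population, knockout) was 0.18. Centred on the 75th percentile these 4 were 0.11, -0.18, -0.11 and 0.035. With cyclic loess the Treg core was 0.13 and oxidative phosphorylation 0.11. With the floor, chemokine receptors (genotype, non-TFR) were 0.065, the Blimp-1 list -0.077 in TFR and 0.11 in non-TFR cells, and germinal centre B cell markers (population, knockout) 0.21. With the mean of all probes, the Treg core and oxidative phosphorylation (population, knockout) were -0.13 and 0.12. Over named probes only, the Treg core and ribosomal proteins (population, control) were 0.13 and -0.13, and the Blimp-1 list -0.11 in TFR and 0.10 in non-TFR cells.

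With list means, the Treg core and Blimp-1 list (population, control) were 0.21 and -0.094, and inhibitory receptors and oxidative phosphorylation (population, knockout) 0.24 and 0.12. On the same basis in the non-TFR genotype comparison, T cell receptor induced and immediate early genes were -0.063, the Blimp-1 list 0.073 and germinal centre B cell markers 0.20. Over members above the median expression, germinal centre B cell markers turned to -0.053 (population, knockout) and were 0.21 in non-TFR cells, and the Blimp-1 list was 0.081 there. Over members above the 75th percentile, the Blimp-1 list turned to -0.12 in non-TFR cells, the Th17 axis was 0.17 (population, control) and 0.091 (genotype, non-TFR), cytokines 0.33 (population, control), effector Treg -0.081 (genotype, TFR), and germinal centre B cell markers 0.43 (population, knockout) and 0.25 (genotype, non-TFR); fewer members remain there by construction.

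Without members shared between lists, the Treg core turned to -0.0053 (population, control) and inhibitory receptors to -0.098 (population, knockout). In the control population comparison the Th17 axis was 0.29, transcription factors 0.18, cytokines 0.19 and inhibitory receptors 0.068. Germinal centre B cell markers were 0.046 (population, knockout), and effector Treg -0.081 (genotype, TFR). In the non-TFR genotype comparison the Th17 axis was 0.17, transcription factors 0.097, the Treg core 0.062, chemokine receptors 0.069, germinal centre B cell markers 0.20 and inhibitory receptors 0.12.

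List medians inside the chance range moved outside it in 30 cases. The effector Treg median (population, knockout) was 0.29 as deposited, 0.14 centred on the 75th percentile, 0.17 with cyclic loess, 0.20 as a mean, 0.18 over members above the median and 0.20 without Gzmb and Il10. With list means, B cell markers were 0.28 (population, control) and 0.20 (genotype, non-TFR), CD8 and NK markers -0.11 and 0.22 (genotype, TFR and non-TFR), and in the knockout population comparison the Th17 axis was 0.33, cytokines 0.23 and myeloid markers 0.20. In the TFR genotype comparison the means were 0.33 (Th17 axis), -0.26 (cytokines), 0.22 (germinal centre B cell markers) and 0.24 (heat shock). With the mean of all probes cytokines were 0.22 (population, knockout). Over members above the median, B cell markers were 0.70 (population, control) and 0.31 (genotype, non-TFR), CD8 and NK markers 0.49 (population, control), -0.34 and 0.31 (genotype, TFR and non-TFR), and in the TFR genotype comparison cytokines were -0.16 and germinal centre B cell markers 0.27. Over members above the 75th percentile, heat shock and myeloid markers were -0.30 and 0.49 (population, knockout), and in the TFR genotype comparison cytokines were -0.28, germinal centre B cell markers 0.54 and myeloid markers 0.26.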

Other observations

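No tests are reported in this part, and the genes in it were chosen after their values were seen.

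Immunoglobulin heavy chain signal was present in these T cell sorts. Of 7 Ighm probes, 2 had means above 12 on the log2 scale, and the brighter of them was at 13.12 in control TFR, 13.31 in knockout TFR, 12.58 in control non-TFR and 13.05 in knockout non-TFR cells. For TFR minus non-TFR these 2 probes differed by 0.55 and 1.63 in the control and by 0.26 and 0.89 in the knockout, and for knockout minus control by 0.19 and 0.48 in TFR and by 0.47 and 1.21 in non-TFR cells, the brighter probe first. Among other B cell genes in the same arrays, Ms4a1 was at 3.98 to 4.12, Cd79a at 5.37 to 5.69, Cd22 at 5.99 to 9.27, H2-Eb1 at 6.46 to 7.53 and Cd79b at 8.08 to 8.42; levels of different probes are not comparable. Xist, the X-inactivation transcript, was 11.38 and 11.44 in control and knockout TFR cells and 10.13 and 10.19 in control and knockout non-TFR cells, which is a difference of 1.25 between the populations in each genotype.

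Probes with several genes or none named were not used above. Of 7016 such probes brighter than the same limit, 64 were at least 2-fold higher and 149 lower in knockout than in control TFR cells, and 60 were higher and 176 lower in non-TFR cells. Between TFR and non-TFR cells, 133 were higher and 201 lower in the control, and 159 were higher and 244 lower in the knockout. The split was opposite in direction to that of named genes in all 4 comparisons.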
